A study of Homo sapiens with 4 samples.

How the data were processed

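Small RNA of extracellular vesicles from human adipose-derived stem cells was measured in 4 libraries, 2 from cells differentiated with SB431542 and 2 without it, each a pool of 3 samples. Per the labels' protocols, vesicles were isolated by differential ultracentrifugation, RNA was extracted with an exosomal RNA kit, and the culture medium held fetal bovine serum. The submitters' processing notes name the genome build GRCh38; the aligner, the read counter, the miRNA annotation and the adapter trimming are not given in the sources used here.

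The deposited table is named as raw counts, but its values are in the reads-per-million unit (RPM), made by the authors before deposit. In every library 1 read is worth a fixed step, and the reciprocal of that step on the RPM scale gives a whole number of reads, taken here as the library total. Of the values above 0, 91.8% and 90.3% without SB431542 and 92.4% and 94.3% with it are whole reads within a tolerance of 0.001 reads, and 100% are multiples of 1/60 of a read, as when a read that fits several miRNAs is split. Because the values are not whole counts, the quasi-likelihood test planned for counts was replaced by limma on log2 values, the choice fixed for that case before the data were examined, and the normalization and test alternatives were run with limma too. The table has 578 entries, 9 of which join names of near-identical miRNAs and 11 of which are hairpins with at most 0.00236% of miRNA reads in any library. A joined entry was matched to a list if any of its names was a member. miRNAs of one family with near-identical sequences can share reads, so values of single let-7, miR-30 and miR-17 family members are uncertain to that extent.

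Reads recovered from the RPM values were scaled by TMM factors, computed with trims of 30% on ratios and 5% on levels, giving factors of 0.859 and 1.35 without SB431542 and 0.925 and 0.930 with it. Values are given as normalized RPM, relative to miRNA reads instead of the whole library. A miRNA was tested if it reached 5.36 RPM of miRNA reads before TMM scaling in at least 2 libraries and 15 reads in all, which left 330 and removed 248. log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust variance moderation using statmod 1.5.0), with the group as the only term and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was required. Fold changes are differences of mean log2(value + 1). This scale shrinks differences between low values above 0, but a single library at 0 can enlarge a fold change or turn its sign against the group means, and a fitted fold of a miRNA with no read in a group can exceed its bound. Higher and lower values are counted by the sign of the log2 fold change. It was opposite to the difference of the group means for 30 of the 330 tested miRNAs, 25 of which had no read in at least 1 library. Where a group had no read, a bound was computed against 3 reads per library, which is 3.02 and 3.52 normalized RPM without SB431542 and 1.17 and 1.26 with it. All p-values are two-sided.

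The 18 miRNA lists, the rule for named miRNAs, the main design and its alternatives were fixed before the data were examined. The 13 lists with at least 3 tested members were tested with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether members move on balance one way without comparing them with other miRNAs. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries, so that setting could hardly call any list. Lists share members, with 41 of 242 names in more than one. Named are miR-20a-5p and its seed family, the 5 miRNAs with the smallest p in each direction because none passed the threshold, the 5 most abundant in each group, and the 2 most abundant tested members of each list. The 4 miR-17-92 members called over their list, miR-21-3p, miR-29b-3p, miR-144-5p, miR-483-5p and miR-1246 were named after their values were seen. So were miR-193b-3p, miR-181b-5p, miR-30b-5p, miR-30e-5p and miR-486-3p. Hairpin positions come from GENCODE 29 on GRCh38.

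The fit was tested on 20 simulated data sets of 330 miRNAs with 40 changed, drawn for 2 against 2 libraries. It recovered 28.8% of 16-fold and 6.0% of 4-fold changes, with a mean of 0.20 false calls, and made 0 calls in the 20 sets without changes. Alternatives were other scalings, low-count filters, moderation without robust weights, the replicate number as a block, removal of the most abundant miRNA, and each library left out in turn. Chosen after seeing the data were the unscaled RPM values, pseudocounts of 0.5 and 5, limma-voom, the block without robust moderation, and the list tests limited to miRNAs with 10 reads in all libraries. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.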

Results

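Small RNA was sequenced from extracellular vesicles, the membrane-bound particles that cells release, collected from human adipose-derived stem cells on day 6 of osteogenic differentiation. The cells had been cultured in osteogenic medium with 10 µM SB431542, an inhibitor of the TGF-β type I receptor kinases, or in the same medium without it. Each group had 2 libraries, and each library pooled 3 samples. The labels do not say whether the pools came from separate donors or cultures, so the p-values measure only the spread between these pools, which may be technical. The deposited reads-per-million (RPM) values imply library totals of 7679475 and 5622523 reads without SB431542 and 13861573 and 7079239 reads with it. Of these, miRNAs took 1156882 and 629634 reads without SB431542 and 2778897 and 2571460 reads with it.

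The vesicle libraries of both groups were dominated by miRNAs abundant in mesenchymal cells. miR-100-5p was the most abundant miRNA in every library, with 25.8% and 16.6% of miRNA reads without SB431542 and 20.7% and 20.2% with it. It was followed in both group means by miR-143-3p, a smooth muscle and mesenchymal miRNA, and miR-21-5p, a miRNA that TGF-β signalling induces in many cell types. The 10 most abundant miRNAs together took 73.8% and 67.4% of miRNA reads without SB431542 and 70.8% and 68.9% with it. miRNAs made up a mean of 13.1% ± 2.73 (SD, n = 2) of the library without SB431542 and 28.2% ± 11.5 (SD, n = 2) with it. The number of miRNA entries above 0 was 316 and 258 without SB431542 and 484 and 419 with it, of 578 in the table. Neither composition measure was tested, since an exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333.

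**Figure D1:**
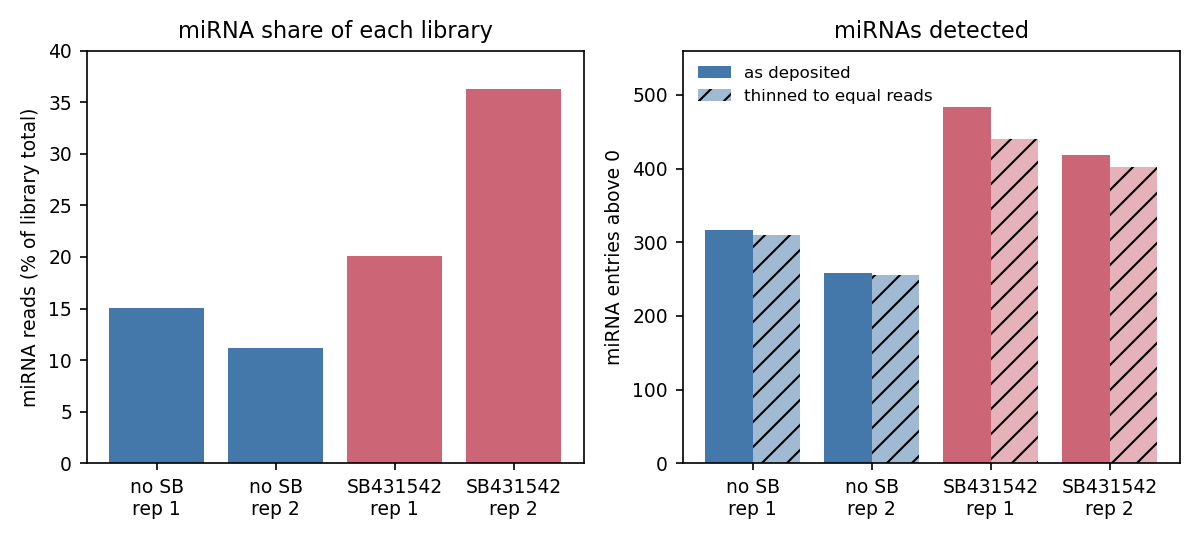
The left panel plots the miRNA reads of each library as a percentage of its total, and the right panel the number of miRNA entries above 0 as deposited (solid) and after thinning every library to 629633 miRNA reads (hatched, mean of 20 draws). Bars are single libraries, and both libraries with SB431542 stand above both without it in each panel, with 440.7 and 402.5 entries against 309.4 and 255 after thinning.

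The comparison of the groups asks which vesicle miRNAs differ when TGF-β receptor signalling is inhibited during osteogenic differentiation. Higher values with SB431542 were found for miR-30a-5p and miR-30c-5p, members of a family that restrains osteogenic differentiation and is repressed by TGF-β in several cell types, and for miR-20a-5p and most measured miRNAs of its clusters. Lower values were found for miR-193b-5p and for miRNAs typical of liver and blood, such as miR-122-5p, miR-486-5p and miR-223-3p. None of these differences passed the threshold for a single miRNA. Of 330 miRNAs tested with limma, 0 were higher and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.104.

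At an unadjusted p under 0.05, limma gave 43 miRNAs with a higher and 15 with a lower value with SB431542. Of the 43, 30 had no read in either library without SB431542, and 13 were seen in both groups. These 30 were all the tested miRNAs with no read in that group. All 3 tested miRNAs with no read in either library with SB431542 were likewise among the 15. Equal zeros give a group no spread, so these p-values mainly restate that the miRNAs were undetected there. By the sign of the log2 fold change 222 tested miRNAs were higher and 108 lower with SB431542, against 196 and 134 by group means. The groups did not overlap for 95 miRNAs with higher and 37 with lower values, 40% of those tested, where chance gives 33.3%. The median log2 fold change was 0.39 over all tested miRNAs and 0.13 over the 197 with at least 10 reads in every library, and it was 1.05 on the deposited scale without rescaling, where the unadjusted counts were 64 higher and 5 lower. limma-voom also called 0 higher and 0 lower, whereas limma without robust variance moderation called 25 higher and 2 lower, of which 24 had no read in either library without SB431542. Leaving out the second library with SB431542 gave 30 higher and 0 lower, and all 30 had no read in either library without SB431542. A filter of at least 10 reads in all libraries gave 0 higher and 4 lower. At an unadjusted p under 0.05 in limma that filter gave 9 higher and 18 lower, with a median log2 fold change of −0.078. With each library left out, the median over all tested miRNAs ranged from 0.075, without the second library lacking SB431542, to 0.56, without the first.

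**Figure D2:**
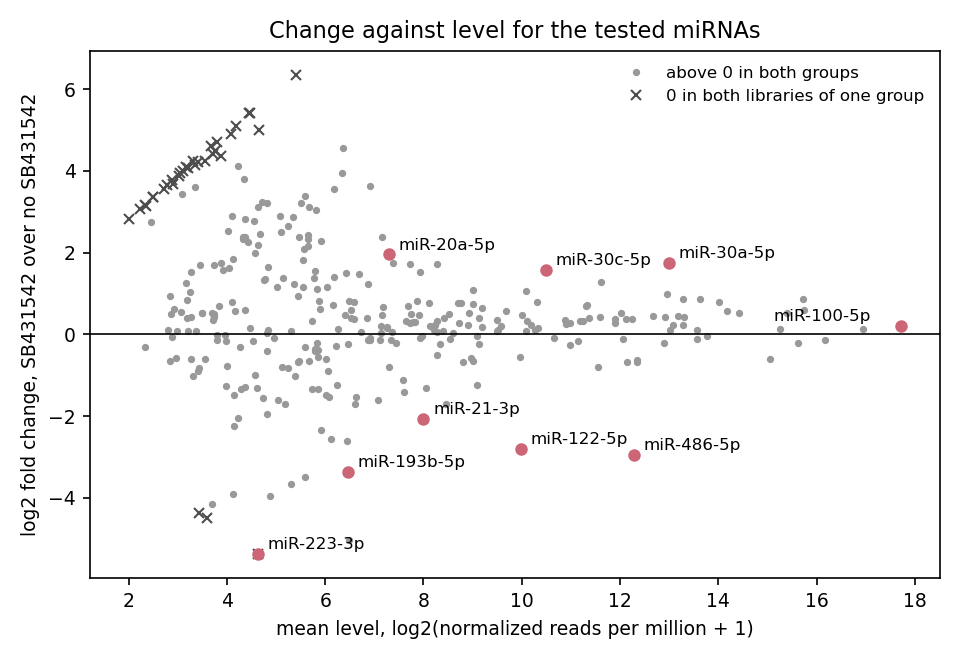
Each point is 1 of the 330 tested miRNAs, placed by its mean level (log2 of normalized RPM plus 1) and its log2 fold change with SB431542 over without it; crosses had no read in both libraries of one group, and the labelled points are miRNAs named in the text. Fold changes spread widely at low levels, while miR-100-5p lies at 0.20 and miR-30a-5p at 1.76.

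miR-20a-5p, which the series title links to BAMBI, a pseudoreceptor that inhibits BMP and activin signalling, had a higher value in both libraries with SB431542 than in either library without it. It is processed from MIR20A on chromosome 13, 91351065 to 91351135 on the plus strand of GRCh38, which is exonic in the host transcript MIR17HG. Its level was 111 and 30.5 normalized RPM without SB431542 and 320.4 and 164 with it, resting on 110, 26, 824 and 392 reads. The log2 fold change was 1.96 (SE 0.82, 95% confidence interval −0.25 to 4.17), with an adjusted p of 0.353 in limma after Benjamini-Hochberg adjustment, so the difference did not exceed the spread between pools by this test. With each library left out the log2 fold change ranged from 1.04, without the second library lacking SB431542, to 2.87, without the first.

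The other measured miRNAs with the seed of miR-20a-5p gave mixed values. miR-93-5p, from an intron of MCM7 on chromosome 7, had 36.8 ± 20.5 normalized RPM without SB431542 and 74.6 ± 5.55 with it (SD, n = 2 each). miR-17-5p, which shares MIR17HG with miR-20a-5p, had no read in one library without SB431542 and 16.4 in the other, against 76.2 and 5.86 with it. miR-106b-5p, also from MCM7, had a log2 fold change of −0.31 (SE 1.31), and this turned to 0.38 on the deposited scale. Of the 4 tested members of the seed family, 3 had higher and 1 had lower values, 0 were called over all miRNAs or adjusted over the list alone, and camera gave an adjusted p of 0.688.

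The wider list of miR-17-92 and its paralog clusters, polycistronic miRNAs associated with proliferation, ranked above the other tested miRNAs with SB431542. Among 13 tested members, 11 had higher and 2 had lower values, and 9 were higher without overlap between groups. The median log2 fold change was 1.96, or 1.55 with undetected members set at their bounds, and 0.49 over the 7 members with at least 10 reads in all libraries. With each library left out it ranged from 1.04, without the second library lacking SB431542, to 2.17, without the second library with it. The camera test with a preset correlation of 0.01 gave an adjusted p of 0.0278 for this list, and the adjusted p was 0.824 with an estimated correlation. The latter setting could hardly call any list with 4 libraries. None (0) of the members were called over all miRNAs, and 4 were called adjusted over the list alone: miR-19a-3p, miR-19b-3p, miR-363-3p and miR-92a-1-5p, none of which had a read in either library without SB431542. All tested miRNAs with no read in those libraries had an unadjusted p under 0.05 in limma. These 4 calls therefore mainly restate that the members were undetected there. The most abundant members gave small differences whose sign changed under other scalings, with log2 fold changes of −0.16 (SE 0.50) for miR-92a-3p, which was 0.68 on the deposited scale, and 0.22 (SE 0.35) for miR-25-3p, which was −0.0016 when scaled by library size. The list's adjusted p in camera was 0.116 over the 7 members with at least 10 reads in all libraries, a filter chosen after seeing the data. It was 0.330 and 0.101 without the first and second library lacking SB431542 and 0.170 without the first library with SB431542.

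**Figure D3:**
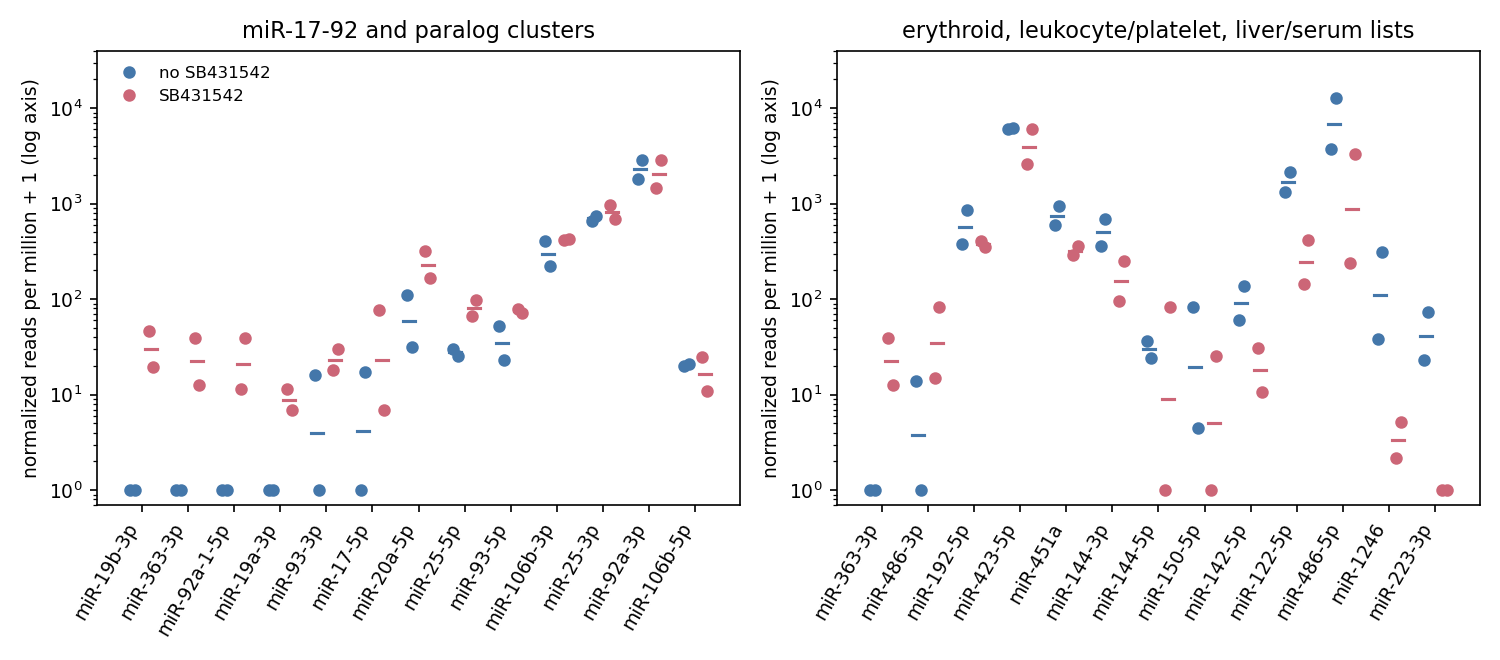
Points are single libraries and short lines the group means on the log scale, in normalized RPM plus 1 on a log axis, for the tested members of the miR-17-92 and paralog clusters (left) and of the erythroid, leukocyte and platelet, and liver and serum lists (right). Members at the foot of the axis had no read; miR-20a-5p had 111 and 30.5 without SB431542 against 320.4 and 164 with it, and miR-122-5p had 1316 and 2171 against 142 and 415.

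Among miRNAs seen in every library, miR-30c-5p and miR-193b-5p had the smallest p in each direction. miR-30c-5p, encoded by MIR30C1 on chromosome 1 and MIR30C2 on chromosome 6, had 722 ± 7.39 normalized RPM without SB431542 and 2151 ± 268 with it (SD, n = 2 each). Its log2 fold change was 1.57 (SE 0.31), with an adjusted p of 0.104 in limma after Benjamini-Hochberg adjustment, and the value was higher in 2 of 2 libraries. miR-193b-5p, from chromosome 16, 14303967 to 14304049, within an intron of MIR193BHG, had 159.6 ± 46.4 without SB431542 and 14.2 ± 2.40 with it (SD, n = 2 each), a log2 fold change of −3.38 (SE 0.66) with an adjusted p of 0.104 in limma. The other arm of that hairpin, miR-193b-3p, was at −0.91 (SE 0.92) with overlap between groups. miR-1271-5p, from an intron of ARL10 on chromosome 5, had 147.6 ± 33.6 without SB431542 and 23.6 ± 7.90 with it (SD, n = 2 each), a log2 fold change of −2.62 (SE 0.62).

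The other miRNAs with the smallest p were undetected in one group. miR-15b-3p, miR-324-3p, miR-328-3p and miR-9903 had no read without SB431542 and were at least 5.49-fold, 4.43-fold, 2.83-fold and 2.84-fold higher with it, taking the mean of each library's limit at 3 reads as the floor. miR-223-3p, a myeloid and platelet miRNA, had 22.1 and 72.8 normalized RPM without SB431542 and no read with it, at least 39.2-fold lower. miR-4449 and miR-181b-3p were likewise undetected with SB431542 and at least 16.2-fold and 18.3-fold lower. These bounds cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The other arm of miR-181b, miR-181b-5p, was at a log2 fold change of 0.20 (SE 0.41) with overlap between groups.

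miRNAs that TGF-β represses included miR-30a-5p and miR-30c-5p, which had higher values. miR-30a-5p, from chromosome 6, 71403551 to 71403621, within an intron of LINC00472, had 3701 ± 819 normalized RPM without SB431542 and 12559 ± 3137 with it (SD, n = 2 each), a log2 fold change of 1.76 (SE 0.37) with an adjusted p of 0.104 in limma. Other members of the miR-30 family gave smaller differences, with a log2 fold change of 0.37 (SE 0.30) for miR-30d-5p. miR-30b-5p and miR-30e-5p, which are not in the TGF-β repressed list, were at 0.24 (SE 0.68) and 0.26 (SE 0.33) with overlap between groups. Of the 6 tested members of the TGF-β repressed list, 5 had higher and 1 had lower values by log2 fold change and 4 and 2 by group means, where miR-29b-3p, with no read in one library, differs. Of these members 0 were called over all miRNAs, and 2 were called adjusted over the list alone, miR-30a-5p and miR-30c-5p. The list itself did not pass, with an adjusted p of 0.615 in camera.

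miRNAs that TGF-β induces did not pass as a list. Of 17 tested members, 11 had higher and 6 had lower values by log2 fold change and 9 and 8 by group means, with a median log2 fold change of 0.12 and a mean of −0.0069, and camera ranked the list below other miRNAs with an adjusted p of 0.519. miR-143-3p had a log2 fold change of 0.14 (SE 0.39) that was −0.073 under library-size scaling, and miR-21-5p one of −0.14 (SE 0.45) that was 0.69 on the deposited scale. miR-21-3p, the other arm of miR-21 and named after its values were seen, was at −2.07 (SE 0.48) without overlap between groups, with an adjusted p of 0.109 in limma, or 0.0456 over miRNAs with at least 10 reads in all libraries. None of the members (0) were called over all miRNAs or adjusted over the list alone.

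The osteogenesis lists did not pass either. Of 13 tested miRNAs that promote osteogenesis, 11 had higher and 2 had lower values by log2 fold change and 10 and 3 by group means, with an adjusted p of 0.519 in camera. miR-10b-5p, a HOXD-locus miRNA, had 38474 ± 10137 normalized RPM without SB431542 and 69218 ± 203 with it (SD, n = 2 each), a log2 fold change of 0.87 (SE 0.35). Of 23 tested miRNAs that restrain osteogenesis, 19 had higher and 4 had lower values by log2 fold change and 17 and 6 by group means, with an adjusted p of 0.688 in camera. miR-100-5p had a log2 fold change of 0.20 (SE 0.54), which was −0.015 under library-size scaling. In both lists 0 members were called over all miRNAs and 0 adjusted over the list alone.

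The mesenchymal, adipocyte, let-7 and DLK1-DIO3 lists did not pass the test. Of 17 tested miRNAs abundant in mesenchymal cells, 14 had higher and 3 had lower values, with an adjusted p of 0.740 in camera. The 8 adipocyte-associated miRNAs split into 4 higher and 4 lower values, with an adjusted p of 0.615 and a downward direction in camera against a median log2 fold change of 0.047, and miR-378a-3p had a log2 fold change of 0.22 (SE 0.32). The 9 let-7 miRNAs, which restrain proliferation, split into 5 higher and 4 lower values, with an adjusted p of 0.688 and a downward direction in camera against a median of 0.12. In this family let-7a-5p was at −0.21 (SE 0.40) and let-7f-5p at 0.12 (SE 0.37), and both changed sign under another scaling, to 0.63 on the deposited scale and to −0.092 under library-size scaling. The imprinted DLK1-DIO3 cluster on chromosome 14 had 43 tested members, 28 with higher and 15 with lower values by log2 fold change and 23 and 20 by group means, the 5 that differ having no read in at least 1 library, with an adjusted p of 0.834 and a downward direction in camera against a median of 0.33. Its most abundant members were miR-127-3p at −0.12 (SE 0.48), which was 0.72 on the deposited scale, and miR-409-3p at 0.33 (SE 0.36). In these 4 lists 0 members were called over all miRNAs or adjusted over the list alone.

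miRNAs of liver and serum and of leukocytes and platelets, which mark other sources of RNA, ranked below the other tested miRNAs with SB431542. All 4 tested liver and serum miRNAs had lower values, with a median log2 fold change of −1.71 and an adjusted p of 0.0191 in camera, and the adjusted p was 0.845 with an estimated correlation. miR-122-5p, the main hepatocyte miRNA, had 1744 ± 605 normalized RPM without SB431542 and 278 ± 193 with it (SD, n = 2 each), a log2 fold change of −2.79 (SE 0.66) with an adjusted p of 0.109 in limma. It was the 1 member called adjusted over the list alone, while miR-423-5p had a log2 fold change of −0.62 (SE 0.51) that was 0.21 on the deposited scale. The 3 tested leukocyte and platelet miRNAs all had lower values, with a median of −2.34, an adjusted p of 0.0191 in camera and an adjusted p of 0.824 with an estimated correlation. For both lists, the setting with an estimated correlation could hardly give a call with 4 libraries. miR-223-3p, which had no read in either library with SB431542, was the 1 member called adjusted over the list alone. miR-142-5p and miR-150-5p had log2 fold changes of −2.34 (SE 0.96) and −1.94 (SE 2.55). Over all miRNAs 0 members of either list were called. The liver and serum adjusted p in camera was 0.236 without the second library lacking SB431542, 0.183 without the first library with it, and 0.116 for members with at least 10 reads in all libraries. The leukocyte and platelet adjusted p ranged from 0.0612 to 0.183 when any 1 library was left out.

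Erythroid miRNAs gave lower values for the abundant members. miR-486-5p had 3714 and 12680 normalized RPM without SB431542 and 238 and 3294 with it, and miR-451a had 769 ± 238 and 322 ± 49.1 (SD, n = 2 each), a log2 fold change of −1.23 (SE 0.40). Of 6 tested erythroid members 4 had lower and 2 had higher values by log2 fold change and 3 and 3 by group means, where miR-144-5p, with no read in one library, differs; 0 were called over all miRNAs or adjusted over the list alone, and camera gave an adjusted p of 0.519 with a median of −1.46 and a mean of 0.022. The second library without SB431542 stood apart from the others on the first principal component (54.4% of variance), at 32.9 against −3.32, −17.6 and −12.0. It held the highest values of miR-486-5p, miR-451a, miR-122-5p and miR-223-3p, but also the fewest entries above 0, with 258. Which miRNAs set it apart on this component was not tested, and miRNAs without a read in it would contribute. On the second component (32.6%) the first library without SB431542 stood apart, at −26.2 against 6.25, 9.52 and 10.4. Over all tested miRNAs the libraries without SB431542 had a Pearson correlation of 0.811. The first of them correlated at 0.837 and 0.846 with the libraries with SB431542, and the second at 0.789 and 0.831. The libraries with SB431542 correlated with each other at 0.913, the highest of all pairs. Over the 197 miRNAs with at least 10 reads in every library, the libraries without SB431542 correlated at 0.948 and those with it at 0.953. Between the groups the values were 0.941 and 0.946 for the first library without SB431542, and 0.892 and 0.937 for the second.

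Markers of other cell types were few. Both endothelial miRNAs had lower values, with log2 fold changes of −0.68 (SE 0.81) for miR-126-3p, which was 0.15 on the deposited scale, and −1.23 (SE 0.75) for miR-126-5p. The 1 tested epithelial miRNA, miR-200b-3p, was at −0.99 (SE 1.45), and the 1 tested muscle miRNA, miR-1-3p, at −1.33 (SE 1.30). No neuronal miRNA and no member of the placental cluster on chromosome 19 reached the level needed for testing.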

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

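The unscaled values, other pseudocounts, limma-voom, the block without robust moderation and the 10-read filter for lists were chosen only after the results were seen.

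With 2 libraries per group the calls depend on how limma moderates the variance. The counts stayed at 0 higher and 0 lower under every other scaling, no low-count filter, both other pseudocounts, limma-voom and removal of miR-100-5p. They became 25 higher and 2 lower without robust moderation, and 0 higher and 4 lower with at least 10 reads in all 4 libraries. Fewer tests do not account for these 4 calls, since the unadjusted p in limma fell too. For miR-193b-5p it fell from 0.00538 to 0.000241, although the SE rose from 0.66 to 0.86 and the log2 fold change went only from −3.38 to −3.58. Moderation over the filtered miRNAs gave the test more degrees of freedom. The count of higher miRNAs ranged from 0 to 30 when each library was left out in turn, the 30 arising without the second library with SB431542, and the lone library was then assumed to vary like the other group. The planned DESeq2 Wald test and edgeR's older quasi-likelihood setting were not run. They were planned for a table of counts, and they were not tried on the reads recovered from the RPM values. Results for other named miRNAs were counted under all alternatives, the replicate block included. Of these, 560 kept their direction and side of the threshold, 27 kept their direction and passed it, and 32 reversed. The replicate block gave 14 of the 27. The cause of the changes below was not tested unless stated.

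The labels give the libraries of both groups the same replicate numbers and the same pool numbers, 1 and 3, but do not say that equal numbers share donors, cultures or days, so pairing was not assumed. Deviations from the group means of same-numbered libraries correlated at 0.14 over 330 tested miRNAs and 0.40 over the 197 with 10 or more reads in every library. The replicate block gave 45 higher and 14 lower, with 1 residual degree of freedom, and the block without robust moderation gave 0 higher and 0 lower. Under the block the log2 fold change of miR-20a-5p was 1.96 with an adjusted p of 0.00670 in limma after Benjamini-Hochberg adjustment, and 0.150 under the block without robust moderation. In other alternatives miR-20a-5p kept its direction, with log2 fold changes from 1.04 without the second library lacking SB431542 to 2.87 without the first, and adjusted p in limma from 0.158 to 0.934.

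Without rescaling, log2 fold changes reversed to 0.38 for miR-106b-5p, 0.69 for miR-21-5p, 0.63 for let-7a-5p, 0.68 for miR-92a-3p, 0.72 for miR-127-3p, 0.15 for miR-126-3p and 0.21 for miR-423-5p; that scale by construction keeps the larger miRNA share with SB431542. Under library-size scaling they reversed to −0.015 for miR-100-5p, −0.073 for miR-143-3p, −0.0016 for miR-25-3p and −0.092 for let-7f-5p, and with 10 reads in all libraries to −0.012 for miR-100-5p, −0.070 for miR-143-3p and −0.089 for let-7f-5p.

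With each library left out, log2 fold changes ranged from −1.02 to 0.27 for miR-106b-5p, −0.45 to 0.85 for miR-100-5p, −0.20 to 0.49 for miR-143-3p, −0.56 to 0.26 for miR-21-5p, −0.57 to 0.011 for let-7a-5p, −0.66 to 0.20 for miR-92a-3p, −0.17 to 0.46 for miR-25-3p, −0.19 to 0.44 for let-7f-5p and −0.67 to 0.29 for miR-127-3p. They ranged from −4.30 to 0.27 for miR-150-5p, −1.51 to 0.15 for miR-126-3p, −2.12 to 0.013 for miR-200b-3p and −2.92 to 0.12 for miR-1-3p.

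No list call held with an estimated correlation or in fry's directional test, but the first of these could hardly call any list with 4 libraries. The estimated correlation was −0.35 for leukocyte and platelet, 0.027 for miR-17-92 and 0.51 for liver and serum. Even where it was negative, for leukocyte and platelet, the unadjusted camera p rose from 0.00293 to 0.0940. Adjusted p for the miR-17-92, leukocyte and platelet, and liver and serum lists were 0.824, 0.824 and 0.845 in limma's camera with an estimated correlation, and 0.0576, 0.0576 and 0.365 in fry's directional test. In fry's mixed test, which asks for change in either direction, adjusted p were 0.0321, 0.0321 and 0.164 for these lists, and they were also under the threshold for the DLK1-DIO3 cluster (0.0321) and the miRNAs that restrain osteogenesis (0.0415). In camera over miRNAs with 10 reads in all libraries they were 0.116 for miR-17-92 and 0.116 for liver and serum. With each library left out they ranged from 0.0193 to 0.330 for miR-17-92, 0.0612 to 0.183 for leukocyte and platelet, and 0.0240 to 0.236 for liver and serum. The block and library-size scaling changed no list call. Entries at 10 or more reads averaged 266 without SB431542 and 381 with it, against 284 and 444.5 at 1 or more. Depth sets the level that 3 reads stand for, 3.02 and 3.52 normalized RPM without SB431542 and 1.17 and 1.26 with it, and a miRNA below that level could go undetected.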

Other observations

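The tests of the ratio of miR-486-5p to miR-122-5p, of the ratio of miR-20a-5p to miR-92a-3p and of level-matched lists were chosen only after the result was seen, as were the miRNAs named in the next paragraph. The rule of the last of these was made stricter after its first value was seen, to hold also with each library left out.

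Outside the rule for named miRNAs, miR-21-3p, the passenger arm of miR-21 and a member of the TGF-β induced list, had 459 and 358 normalized RPM without SB431542 and 127.5 and 71.5 with it, a log2 fold change of −2.07 (SE 0.48), while miR-21-5p was at −0.14 (SE 0.45). miR-483-5p, from an intron of the fetal growth factor gene IGF2, had 67.4 and 106.8 without SB431542 and 3.89 and 10.9 with it. miR-1246, a miRNA often reported in serum and vesicles, had 37.2 and 313 without SB431542 and 1.17 and 4.18 with it. With only the 197 miRNAs at 10 or more reads in all libraries, limma called 4 lower and 0 higher after Benjamini-Hochberg adjustment: miR-122-5p at an adjusted p of 0.00163, miR-193b-5p at 0.0237, miR-483-5p at 0.0249 and miR-21-3p at 0.0456. These calls depend on how the variance is moderated over the filtered miRNAs.

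More miRNA entries were detected with SB431542 than without it, 64 being present in both libraries with SB431542 and neither without, against 4 the other way. When the libraries were split by replicate number, 24 entries were present only in both libraries of the first number, against 0 the other way. The remaining split gave 9 and 7. Depth alone is argued against, since after thinning to equal miRNA reads the groups still differed by a mean of 139.4 entries. Fewer distinct RNA molecules before amplification in either or both libraries without SB431542 may account for the difference between the groups. Entries with 50 or more reads in one replicate and 0 in the other were 18.5 times as many without SB431542 (9.25 against 0.50, mean of draws). This count does not tell which library lost molecules, and any other difference between the pools without SB431542 would raise it too. A change in the vesicles' miRNA content caused by the inhibitor stays open, since neither RNA input nor molecule counts were analysed here.

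Blood, liver and serum miRNAs had lower values with SB431542, with 11 of the 13 members of the erythroid, leukocyte and platelet, and liver and serum lists lower by log2 fold change after scaling and 10 lower by group means. A larger miRNA share could dilute RNA of constant amount, such as RNA from fetal bovine serum in the medium. Relative to the whole library the members' median log2 fold change was −0.47 (95% bootstrap interval over members −1.94 to 0.21). The prediction written beforehand expected an interval including 0 under dilution, and this one does. The test as run also required a narrower interval. Since this one is wide and the members go both ways, the question was left undecided. A single outside source of fixed profile was examined with the ratio of miR-486-5p to miR-122-5p, which was 2.82 and 5.84 without SB431542 and 1.67 and 7.95 with it. Its range lay at percentile 86.1 of matched miRNA pairs, between the bounds set for and against such a source. Serum RNA, blood cells in the tissue isolate and an effect of the inhibitor cannot be told apart for these miRNAs, because no library of unconditioned medium was analysed here.

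miR-20a-5p and most of its cluster had higher values with SB431542. Reads split in fractions with near-identical miRNAs are argued against for miR-20a-5p, since its reads were not whole in 0 of the 4 libraries. Reads of such miRNAs counted whole as miR-20a-5p would not show in this test. One change of the shared MIR17HG transcript could not be decided: the log2 ratio of miR-20a-5p to miR-92a-3p was 2.14 higher with SB431542, but the groups overlapped (−4.04 and −6.55 against −2.18 and −4.15), and miR-92a-3p also comes from a copy on the X chromosome. Whether few distinct molecules without SB431542 contribute was not decided: the list's median lay at percentile 99.45 of 10000 lists matched on level, which argues against this, but between 92.3 and 98.4 with any 1 library left out, several members being near the floor. An effect of the inhibitor stays an open hypothesis.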
